A study of Mus musculus with 6 samples.

How the data were processed

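RNA sequencing libraries from the livers of 6 mice, 3 labelled HuR flox/flox (flox) and 3 labelled hepatocyte-specific HuR knockout (HKO), were compared. The groups were taken from the sample labels. Per the labels' protocols, livers were flash frozen, total RNA was extracted with TriPure and libraries were prepared by a standard Illumina procedure. The labels treat the mice as separate samples and give no batch, litter or date. The submitters' processing notes name TopHat2, HTSeq 0.6.1 and the genome build GRCm38.p6, without further settings. Whether reads were counted by strand was not given in the sources used here, so a gene and an overlapping antisense gene cannot be told apart.

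The authors deposited FPKM values, which are scaled to gene length and library size, in 1 table per group with the same genes in the same order, per the file headers. Each table also gives the gene's name, position, length and biotype. Multiplying each FPKM by the gene's length gave whole multiples of the value of 1 read for 100% of the values above 0 in every library (tolerance 0.01 of a read), so reads could be recovered. The library sizes inside the deposited FPKM values equalled median-of-ratios size factors computed over these 6 libraries together, so both tables share 1 normalization. Scaling by median ratios again therefore changed nothing. Total reads per library were between 16769082 and 20633215. The effect of depth was not tested.

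Values were analysed as log2(FPKM + 0.5), so fold changes understate the change of genes with low values. Genes with a mean of at least 0.5 FPKM over the 6 libraries (13787) were tested with limma 3.58.1 in R 4.3.3, with a linear model of group, moderated variances with a mean-variance trend, two-sided tests and Benjamini-Hochberg adjustment, at a threshold of 0.05. The prior degrees of freedom were 2.76. Gene lists were compared with the other genes by limma's camera with a preset correlation of 0.01, for lists with at least 5 tested members, with camera at an estimated correlation beside it. Limma's fry was also run, which tests each list against no change and not against the other genes. Counts adjusted over the list alone apply the Benjamini-Hochberg adjustment to the members of a list only. A fold change of HKO against flox is positive where libraries labelled HKO are higher.

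The groups, the test, the 41 gene lists and the rule for naming genes were fixed before the data were examined. That rule took Elavl1, then up to 12 genes each way with the largest change among protein-coding genes that passed, had a mean of at least 1 FPKM, did not overlap between groups and carried a gene name other than a clone or model number. Of each list it took up to 4 members that passed, or the 2 with the smallest p, given as values. Few genes passed, so members past the threshold adjusted over the list alone were named as well, and this extension was made after the values were seen. Some genes that the rule or its extension would name are not reported here. Made after the values were seen, too, was the choice of Adgre1, Apob, Uqcrb, Col1a1, Saa1, Saa2, Saa4, Fgb, Crp, Hamp, Cela1, Try5 and Xist.

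Alternatives fixed beforehand were pseudocounts of 0.1 and 1, no filter, a filter at 2 FPKM, 4 other scalings, moderation without trend or robustly, a replicate block, protein-coding genes alone, voom on the recovered reads, a log2 fold limit of 1, a threshold of 0.1, an estimated correlation, and leaving out each library. Added after seeing the data were removal of each library's trend with gene length (lowess of each gene's deviation on log2 length, span 0.3), the same with the replicate block, leaving out flox 2 and HKO 3, and 2 fits with library weights. AU-rich sequence was searched in annotated 3' UTRs of GENCODE M21, which is on the GRCm38 assembly.

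The code was tested on simulated data for the comparison of HKO with flox: reads were drawn for the real genes with the measured means, library sizes and spread within groups, and 200 genes per simulation were changed, in 10 simulations. That spread was pooled over both groups for each gene and drawn independently. The wider spread of the flox libraries and outlying libraries were thus not modelled, so the percentages may not hold for these libraries. With about 13614 genes tested, 6.40% of 2-fold, 53.4% of 4-fold, 82.6% of 8-fold and 91.0% of 16-fold changes were recovered, and 6.10 unchanged genes were called per simulation. In these simulations, where genes vary independently, camera called 0.200 lists on average. The spread within groups limited what could be called: with the spread at 0.25 of that measured, 87.8% of 2-fold changes were recovered, with about 13636 genes tested. Figures were drawn with matplotlib 3.10.9.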

Results

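Liver RNA from 6 C57BL/6 mice was profiled by RNA sequencing. In 3 mice (labelled flox) the gene for the RNA-binding protein HuR carried loxP sites on both alleles, and 3 mice (labelled HKO) were hepatocyte-specific HuR knockouts per the labels. All were fed a diet that the labels call MCD for 3 weeks and were 11 weeks old when the livers were taken. The comparison of the 2 genotypes on this diet asks which liver transcripts depend on hepatocyte HuR. The tables held FPKM values, from which the underlying whole reads were recovered. Reads assigned to genes numbered 18329040, 18040015 and 18119468 in flox 1, 2 and 3, and 16769082, 18406482 and 20633215 in HKO 1, 2 and 3. Of the genes, 13787 had a mean of at least 0.5 FPKM over the 6 libraries and were tested.

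The HKO libraries resembled one another more than the flox libraries did. Pearson's r across the tested genes was 0.957 to 0.978 between HKO libraries and 0.811 to 0.947 between flox libraries, on the log2(FPKM + 0.5) scale. Genes are not independent replicates in these values. Flox 2 had reads in 16608 genes, against 19920 to 22067 in the other libraries, and 2.26% of its reads were mitochondrial, against 4.34% to 4.69%. The first principal component held 59.0% of the variance, with flox 1 at -37.3, flox 2 at -101 and flox 3 at 41.4. The HKO libraries lay at 23.0 to 40.9, so flox 3 fell on their side. The second component held 23.8% and set flox 3 apart. Between groups r was 0.827 to 0.940. Flox 3 had r of 0.918, 0.919 and 0.896 with HKO 1, 2 and 3, and 0.897 and 0.811 with flox 1 and 2. Xist, a transcript of the inactive X chromosome in females, was at 0.0109 FPKM or less in every library. The Y-linked gene Ddx3y lay between 1.53 and 11.5 FPKM in all 6.

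Elavl1, the gene that encodes HuR, was not lower in the libraries labelled HKO. It lies on chromosome 8 from 4285382 to 4325413 of GRCm38.p6, on the minus strand, with identifier ENSMUSG00000040028 and a length of 10363 bases in the tables. Its level was 3.51, 2.36 and 2.99 FPKM in flox 1, 2 and 3 and 5.77, 4.28 and 4.91 FPKM in HKO 1, 2 and 3. The means were 2.95 ± 0.579 FPKM (SD, n = 3) in libraries labelled flox and 4.98 ± 0.750 FPKM (SD, n = 3) in those labelled HKO. The log2 fold change, HKO minus flox, was 0.67 with an SE of 0.23 and did not pass the threshold (limma, Benjamini-Hochberg adjusted p = 0.208). The 3 values of each group did not overlap, which gives an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. After removal of the gene length trend of each library the value was 0.32 with an SE of 0.24 (limma, adjusted p = 0.455, range over all alternatives 0.0516 to 0.640). The values sum reads over the whole gene, so reads from exons outside the deleted part and from other liver cells count as well, and the exons removed were not given in the sources used here. Because the target gene ran against the genotype labels, each direction below is between libraries labelled HKO and libraries labelled flox.

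**Figure D1:**
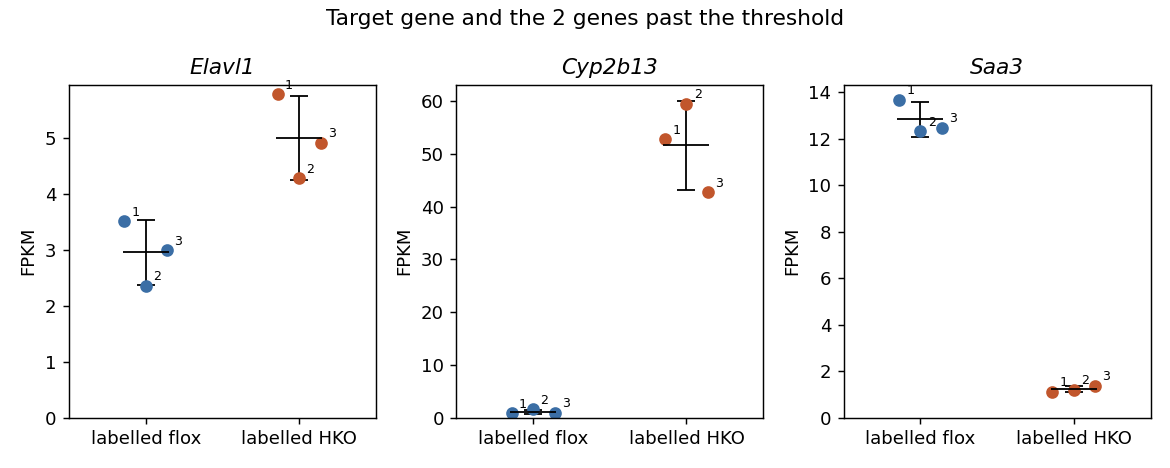
FPKM per library (vertical axes, linear, starting at 0) of Elavl1, Cyp2b13 and Saa3 in the 3 libraries labelled flox and the 3 labelled HKO; points carry the replicate number, bars give the mean and SD. Elavl1 averaged 2.95 FPKM in flox and 4.98 in HKO, Cyp2b13 1.14 and 51.6, and Saa3 12.8 and 1.23.

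A cytochrome P450 gene and an acute-phase gene passed the threshold over all genes. Cyp2b13, a drug-metabolizing cytochrome P450 that is higher in female than in male mouse liver, was 32-fold higher in the libraries labelled HKO. It had 0.893, 1.56 and 0.975 FPKM in flox 1, 2 and 3 and 52.7, 59.5 and 42.7 FPKM in HKO 1, 2 and 3, a log2 fold change of 5.0 with an SE of 0.25 (limma, Benjamini-Hochberg adjusted p = 0.00353). Saa3, a serum amyloid A gene of the acute-phase response, was lower in the libraries labelled HKO, with 13.7, 12.3 and 12.5 FPKM in flox and 1.11, 1.21 and 1.37 FPKM in HKO. Its log2 fold change was -2.95 with an SE of 0.19 (limma, adjusted p = 0.00972). Cyp2b13 lies on chromosome 7 from 26061497 to 26096197, on the plus strand. Both belong to families of similar genes, so reads shared with paralogs such as Cyp2b9 could be split between members. At an unadjusted p below 0.05 there were 2877 genes, 1393 higher and 1484 lower in the libraries labelled HKO, where 689 would be reached by chance if genes were independent. Other splits of the 6 libraries into 3 and 3 gave 73 to 1711. The groups did not overlap for 4401 genes (31.9%), where chance gives 10% on average. This share was not computed for the other splits, so how far it strays from 10% without a group difference is not known.

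These counts hung on single libraries, through the p-values more than through the folds of the 2 genes. Without flox 3, limma called 2897 genes higher and 2678 lower in the libraries labelled HKO, 5575 of the 13787 tested, with both of the genes above among them. Counts of list members without flox 3, given below, stand against that share of all genes. Flox 1 and 2, the flox libraries left, had slopes on log2 gene length of -0.040 and -0.142, against 0.038 to 0.049 in HKO. Genotype and this trend cannot be told apart there, and the fit was not repeated with the length correction. Without flox 1 or without HKO 2 limma called 0 genes, with 1904 and 1236 at an unadjusted p below 0.05. Cyp2b13 then had an adjusted p of 0.0828 and 0.0719, at a log2 fold change of 4.89 in both. Without HKO 3 Cyp2b13 was the 1 gene called, and without HKO 1 there were 2 genes higher and 0 lower. Saa3 had an adjusted p of 0.197 without flox 1, 0.157 without HKO 1, 0.191 without HKO 2 and 0.203 without HKO 3, at log2 fold changes of -2.90, -2.90, -2.94 and -3.01. Over all alternatives the adjusted p ranged from 0.00127 to 0.0903 for Cyp2b13 and from 0.00587 to 0.567 for Saa3. Leaving out flox 2 and HKO 3 together, a choice made after seeing the data, left 0 genes past the threshold and 1097 at an unadjusted p below 0.05.

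Of 41 gene lists fixed beforehand, 40 had enough tested members for a set test. By limma's camera with a preset correlation of 0.01, 7 passed as higher and 12 as lower in the libraries labelled HKO. None passed with a correlation estimated from the data, where the smallest adjusted p was 0.532. By fry, which tests a list against no change and not against other genes, none passed either, with a smallest adjusted p of 0.0532. Of the lists, 10 passed fry's test for change in either direction. All set test p-values below are Benjamini-Hochberg adjusted over the 40 lists. Apart from Cyp2b13 and Saa3, no gene named below passed over all genes. "Rose" and "fell" of other single genes therefore refer to limma's test adjusted over the list alone.

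Acute-phase genes of the liver were lower in the libraries labelled HKO. The acute-phase and complement list had 26 of 36 tested members with negative values, a median log2 fold change of -0.60 and a set test adjusted p of 3.02e-05 (limma camera). Its adjusted p = 0.695 with an estimated correlation. Of the members 10 fell and 0 rose adjusted over the list alone, against 1 (Saa3) over all genes. Lcn2, an iron-binding secreted protein, was at 544 ± 7.91 FPKM (SD, n = 3) in flox and 89.0 ± 32.7 in HKO, a log2 fold change of -2.67 with an SE of 0.29. Hpx, which encodes the heme carrier hemopexin, fell by 2.42 on the log2 scale, and Orm1, an orosomucoid, fell by 1.91. Flox 3 stood apart in this list, and without it the adjusted p was 0.0263, with 14 members lower and 4 higher over all genes. Saa1 was at 702 FPKM in flox 3, against 54.5 and 56.2 in flox 1 and 2 and 3.81 to 6.48 in the libraries labelled HKO. Quantile normalization ended the list's call (adjusted p = 0.0563, range over alternatives 4.57e-09 to 0.695).

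Markers of neutrophils and macrophages were lower as well. All 6 tested neutrophil genes had negative values, with a median of -1.81 (limma camera, adjusted p = 5.39e-06, and adjusted p = 0.532 with an estimated correlation), and 6 fell adjusted over the list alone, against 0 over all genes. S100a9, a calcium-binding protein abundant in neutrophils, was at 22.8 ± 8.53 FPKM (SD, n = 3) in flox and 1.66 ± 0.60 in HKO. S100a8, its partner, had 11.9 ± 5.73 and 1.17 ± 0.0211 FPKM. The macrophage and Kupffer cell list had 23 of 27 members negative and a median of -0.94 (limma camera, adjusted p = 1.29e-06, and adjusted p = 0.532 with an estimated correlation). There 5 members fell adjusted over the list alone and 0 over all genes. Without flox 3 the count over all genes was 18 lower and 1 higher. Gpnmb, a gene of lipid-laden macrophages, fell by 3.33 on the log2 scale, Lgals3 (galectin-3) by 2.97 and Cd14, a co-receptor for bacterial lipopolysaccharide, by 1.95. Adgre1, which encodes the macrophage antigen F4/80, was at 12.4 ± 2.23 FPKM in flox and 12.9 ± 2.35 in HKO.

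Inflammatory cytokines and chemokines had 29 of 35 members negative and a median of -0.48 (limma camera, adjusted p = 0.00290, and adjusted p = 0.695 with an estimated correlation). Cxcl2 fell by 1.14 and Ccl9 by 1.15 adjusted over the list alone, against 0 genes over all genes. Without flox 1 the list's adjusted p was 0.0662 (range over alternatives 3.08e-05 to 0.695). The interferon response list had 22 of 30 members negative and a median of -0.32 (limma camera, adjusted p = 0.0384, and adjusted p = 0.695 with an estimated correlation), and its member Zbp1, a sensor of nucleic acids, fell by 1.26 adjusted over the list alone. This call ended without flox 1 (0.343), without HKO 1 (0.0858) and after the length correction (0.0771), in a range of 0.00280 to 0.695. Without flox 3 the adjusted p was 0.000125 for cytokines and 0.00581 for interferon. The counts over all genes were then 18 lower and 1 higher for cytokines and 14 lower and 0 higher for interferon. In both lists flox 3 lay near the libraries labelled HKO: its mean deviation was -0.25 for cytokines, against 0.57 and 0.42 in flox 1 and 2.

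**Figure D2:**
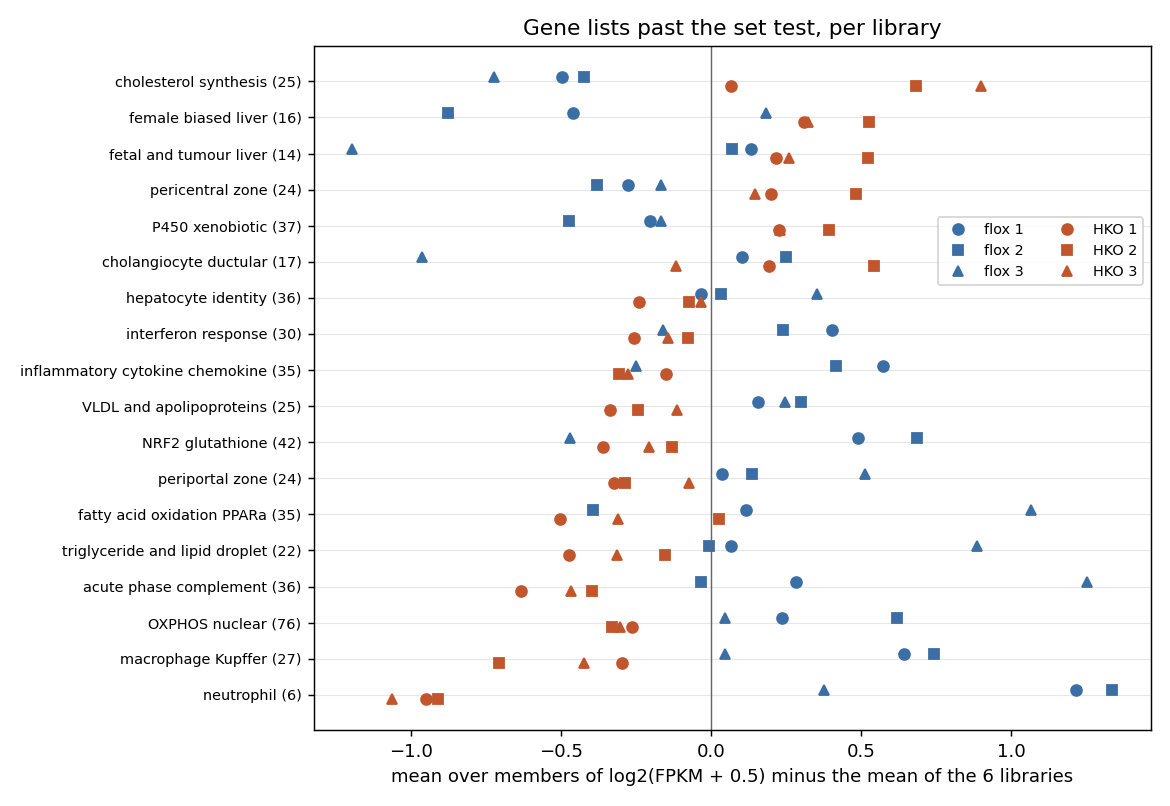
Mean over the tested members (number in brackets) of log2(FPKM + 0.5) minus the mean of the 6 libraries, horizontal axis, for 18 of the gene lists past the set test, one row per list; colour gives the label and the symbol the replicate number. Cholesterol synthesis lay from -0.72 to -0.42 in flox and from 0.06 to 0.90 in HKO, and flox 3 stood at 1.25 for the acute-phase list.

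Genes of cholesterol synthesis were higher in the libraries labelled HKO. Of 25 tested members 24 had positive values, with a median of 0.97 (limma camera, adjusted p = 1.90e-07, and adjusted p = 0.532 with an estimated correlation). Of these, 10 rose and 0 fell adjusted over the list alone, against 0 over all genes. Sqle, which encodes squalene epoxidase, had 2.46 ± 0.342 FPKM (SD, n = 3) in flox and 12.3 ± 2.78 in HKO, a log2 fold change of 2.09 with an SE of 0.24. Idi1, an isomerase of the isoprenoid pathway, rose by 3.68 and Cyp51, a sterol demethylase, by 2.26. HKO 1 was the lowest of the libraries labelled HKO for these enzymes, with 4.70 FPKM of Idi1 against 15.2 and 17.4. In flox 1, 2 and 3 Idi1 had 0.478, 0 and 0.931 FPKM. Its log2 fold change was 2.93 to 6.06 over the alternatives.

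Genes of lipid transport, of triglycerides and lipid droplets, and of fatty acid oxidation went the other way. The list of apolipoproteins and lipoprotein genes had 19 of 25 members negative and a median of -0.50 (limma camera, adjusted p = 0.000913, and adjusted p = 0.532 with an estimated correlation), and adjusted over the list alone 6 fell and 1 rose, against 0 over all genes. Apoc3, an inhibitor of lipoprotein lipase, fell by 1.25 on the log2 scale and Apoa5, its counterpart that favours lipolysis, by 1.10. The triglyceride and lipid droplet list had 19 of 22 negative and a median of -0.56 (limma camera, adjusted p = 0.000913, and adjusted p = 0.532 with an estimated correlation), with 0 members past the threshold adjusted over the list alone. Its lipid droplet gene Cidec had 77.3, 87.5 and 281 FPKM in flox 1, 2 and 3 and 16.3 to 31.6 FPKM in HKO. Flox 3 lay 0.89 above the mean of the 6 libraries in this list, flox 1 and 2 at 0.07 and -0.01, and without flox 3 the adjusted p was 0.0380, with 8 members lower and 1 higher over all genes. Fatty acid oxidation genes had 29 of 35 negative and a median of -0.52 (limma camera, adjusted p = 0.00257, and adjusted p = 0.695 with an estimated correlation), and Acaa1a, a peroxisomal thiolase, fell by 1.21 adjusted over the list alone. Here flox 3 lay 1.07 above the mean of the 6 libraries, and without it the adjusted p was 0.388, against 1.09e-06 without flox 2 (range over alternatives 1.09e-06 to 0.695). Quantile normalization ended these 3 calls (0.509, 0.0819 and 0.509, in the order given).

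Lipogenesis as a list did not pass (14 of 19 positive, median 0.26, limma camera adjusted p = 0.112), except as higher after quantile normalization (0.0115). Adjusted over the list alone 2 of its members rose, Acly, which makes cytosolic acetyl-CoA, by 1.30 and the fatty acid elongase Elovl6 by 1.33. Bile acid genes moved both ways (15 of 26 positive, limma camera adjusted p = 0.837), and adjusted over the list alone 4 rose and 2 fell. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 10.4 ± 1.68 FPKM (SD, n = 3) in flox and 50.7 ± 22.8 in HKO, a log2 fold change of 2.15. The canalicular bile salt pump Abcb11 rose by 1.66, and the basolateral exporters Abcc3 and Abcc4 fell by 1.0 and 1.12. Neither list had a member past the threshold over all genes.

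Cytochrome P450 genes and genes of the pericentral zone, the region around the central vein, were higher in the libraries labelled HKO. The P450 list shares members with the pericentral list, such as Cyp2c37, and with the female-biased list below, such as Cyp2b13. Their calls are therefore not separate results. The P450 and xenobiotic list had 26 of 37 positive and a median of 0.40 (limma camera, adjusted p = 0.00298, and adjusted p = 0.532 with an estimated correlation; 0.0531 without flox 3, range from 6.3e-06). In this list 11 members rose and 3 fell adjusted over the list alone, against 1 (Cyp2b13) over all genes. Cyp3a11 rose by 1.60, from 226 ± 49.4 FPKM (SD, n = 3) in flox to 680 ± 64.4 in HKO, and Cyp2b10, a target of the xenobiotic receptor CAR, by 2.08, while Por, the electron donor of microsomal P450 enzymes, fell by 1.53. The pericentral list had 18 of 24 positive and a median of 0.53 (limma camera, adjusted p = 0.000921, and adjusted p = 0.532 with an estimated correlation), and 6 rose adjusted over the list alone, against 0 over all genes. Among them Cyp2c37 rose by 1.92 and Lgr5 by 1.21. Periportal genes had 17 of 24 negative and a median of -0.51 (limma camera, adjusted p = 0.0105, and adjusted p = 0.695 with an estimated correlation; 0.142 without flox 3 and 0.919 after quantile normalization, range from 0.000721). Adjusted over the list alone 5 fell, among them Sds, a serine dehydratase, by 1.85, and over all genes 0. Without flox 3, 9 periportal members were lower and 4 higher over all genes.

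Genes known to be higher in female liver had 13 of 16 positive values and a median of 0.70 (limma camera, adjusted p = 0.00298, and adjusted p = 0.532 with an estimated correlation). Of these genes 4 rose adjusted over the list alone (Cyp2b13, Slc22a27, Slc22a26 and Cyp2b9), against 1 over all genes. The male-biased list did not pass (10 of 19 negative, limma camera adjusted p = 0.362), with the major urinary protein gene Mup21 that rose by 2.33 and Cyp4a12b and Cyp4a12a that fell by 1.5 and 1.56 adjusted over the list alone. Fetal and tumour liver genes had 11 of 14 positive and a median of 0.59 (limma camera, adjusted p = 0.0305, and adjusted p = 0.695 with an estimated correlation; 0.565 without flox 3, 0.0535 without HKO 2, 0.0868 with equalized sums, 0.0735 without the 50 most abundant genes in the totals, 0.0545 after quantile normalization and 0.0605 with protein-coding genes alone, range from 0.00172). Cholangiocyte and ductular genes had 11 of 17 positive and a median of 0.25 (limma camera, adjusted p = 0.0384, and adjusted p = 0.718 with an estimated correlation; 0.970 without flox 3, 0.00165 without flox 2, 0.0856 without HKO 2, 0.0793 with the filter at 2 FPKM, and 0.0880, 0.0735 and 0.0608 under the same 3 scalings, range from 2.86e-05). Of the former 2 rose adjusted over the list alone, Robo1 by 1.08 and Tspan8 by 1.89, and of the latter 3, Epcam by 1.72, Spp1 by 1.54 and Pkhd1 by 1.05. Neither had a member past the threshold over all genes.

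Nuclear genes of oxidative phosphorylation were lower almost throughout. Of 76 tested members 70 had negative values, with a median of -0.64 (limma camera, adjusted p = 8.05e-13, and adjusted p = 0.532 with an estimated correlation), but 0 passed adjusted over the list alone or over all genes. Without flox 3, over all genes, 50 were lower and 1 higher. Ndufa12, a subunit of complex I, had 20.7 ± 4.70 FPKM (SD, n = 3) in flox and 9.58 ± 1.29 in HKO (log2 fold change -1.06, SE 0.24). These are short genes, with a median length of 1737 bases, and after the length correction the median was -0.48 (limma camera, adjusted p = 5.72e-09, and adjusted p = 0.612 with an estimated correlation). The 13 protein genes of the mitochondrial genome did not pass as a list (9 negative, limma camera adjusted p = 0.362, and 0.0171 without flox 2). The glutathione and NRF2 list had 35 of 42 negative and a median of -0.51 (limma camera, adjusted p = 0.00361, and adjusted p = 0.718 with an estimated correlation). Without flox 1 and without flox 2 its adjusted p was 0.0674 and 0.0950, without flox 3 6.6e-07, after quantile normalization 0.661 (range from 6.6e-07), and flox 3, at -0.47, lay below all libraries labelled HKO. Gpx3, a secreted glutathione peroxidase, fell by 1.57 adjusted over the list alone. Without flox 3, 30 members were lower and 0 higher over all genes. Hepatocyte identity genes had 26 of 36 negative and a median of -0.27 (limma camera, adjusted p = 0.0325, and adjusted p = 0.695 with an estimated correlation; 0.184 without flox 3, 0.10 without HKO 1, 0.311 after the length correction, 0.0994 with the filter at 2 FPKM, 0.123 with equalized sums and 0.119 without the 50 most abundant genes in the totals, range from 0.00388), with 0 past the threshold adjusted over the list alone. After quantile normalization the hepatocyte identity list turned to higher without passing (limma camera, adjusted p = 0.167). Without flox 3, 7 of its 36 members were lower and 4 higher over all genes, against 2678 lower and 2897 higher among the 13787 genes tested.

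Known HuR targets did not pass as a list, and HuR with related RNA-binding proteins passed under some alternatives alone. Of 27 tested targets from the literature 14 had positive and 13 negative values (limma camera, adjusted p = 0.620), with 0 past the threshold adjusted over the list alone. Without flox 3, limma called 9 of them higher and 5 lower over all genes. Values for the cell cycle gene Ccnd1 were 17.0 ± 13.8 FPKM (SD, n = 3) in flox and 56.7 ± 5.97 in HKO. Apob had 244 ± 96.9 and 296 ± 49.0 FPKM, and Uqcrb 139 ± 19.8 and 112 ± 10.9. HuR (Elavl1 itself), its relatives and other binders of AU-rich RNA had 10 of 15 positive and a median of 0.31 (limma camera, adjusted p = 0.0780), with 0 past the threshold adjusted over the list alone. This list passed as higher with equalized sums (0.0342), without the 50 most abundant genes in the totals (0.0349), after quantile normalization (0.0115) and without flox 3 (0.0240, with 4 members higher and 0 lower over all genes). It did not pass with an estimated correlation (limma camera, adjusted p = 0.718) or after the length correction (0.237, median 0.20).

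The circadian clock list did not pass in one direction (limma camera, adjusted p = 0.151), but 4 members rose and 2 fell adjusted over the list alone, against 0 over all genes. Nr1d1, a repressor of the clock, fell by 1.93, from 5.68 ± 1.04 FPKM (SD, n = 3) to 1.12 ± 0.289, and Dbp by 2.21. Per2 rose by 1.32, Cry1 by 1.41, Arntl by 1.18 and Bhlhe40 by 0.74. In the fibrosis and matrix list (31 of 41 negative, limma camera adjusted p = 0.112) Mmp12, a macrophage elastase, fell by 2.32 adjusted over the list alone. Col1a1 had 15.9, 28.0 and 3.83 FPKM in flox 1, 2 and 3 and 3.19 to 6.06 FPKM in HKO, and the list's adjusted p was 0.0148 without flox 3, 0.0467 without HKO 1, 0.0338 without HKO 2, 0.0363 with no filter and 0.0349 with the replicate block. Cell cycle genes (26 of 35 negative, limma camera adjusted p = 0.112, and 0.784 with an estimated correlation) gave 0.000125 without flox 3 and turned to higher without flox 1 (0.696). They passed as lower with no filter (0.00930), equalized sums (0.0157), totals without the 50 genes (0.0203) and quantile normalization (0.0186), with flox 1 the highest library and flox 3 the lowest. Of the methionine, choline and one-carbon list (16 of 30 positive, limma camera adjusted p = 0.620, and 0.0256 after quantile normalization) Cth, which makes cysteine from cystathionine, rose by 1.66 adjusted over the list alone. Pcx, the first enzyme of gluconeogenesis from pyruvate, fell by 1.06 and the stress sensor Ern1 rose by 1.46 in lists that did not pass as a whole (0.620 for gluconeogenesis and glycolysis, 0.912 for the unfolded protein response).

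Other lists that did not pass were p53 and apoptosis (limma camera, adjusted p = 0.487), PI3K and AKT signalling (0.151), class II antigen presentation (0.151), T and NK cells (0.119), B and plasma cells (0.837), stellate cells (0.857), sinusoidal endothelium (0.850), blood (0.293) and adipose tissue (0.425). Adjusted over the list alone, Car3 of the adipose list, also a liver gene, rose by 2.18, and no member of the rest passed. Medians and tests differed in sign for stellate cells (median 0.09, test lower) and for the unfolded protein response (median -0.08, test higher). Antigen presentation gave 0.0182, T and NK cells 0.00531 and the PI3K list 0.0206 without flox 3. T and NK cells passed as lower also with no filter (0.0193), equalized sums (0.0136), totals without the 50 genes (0.0174) and quantile normalization (0.0194). Antigen presentation did so with the filter at 2 FPKM (0.0411), equalized sums (0.0214), totals without the 50 genes (0.0214) and the replicate block (0.0346). The sex chromosome list had 4 tested members, too few for the set test, all with positive values.

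Transcripts of pancreatic digestive enzymes were present in HKO 3. The 16 genes of the pancreas list took 1.61% of the reads of HKO 3, 0.0169% of HKO 2 and 0.00106% to 0.00272% of the other libraries. In flox most of these reads were of Cela1 (303, 466 and 177 reads), and 4 or 5 of the 16 genes had reads. HKO 1 had reads of 15 genes, among them 28 of the trypsin gene Try5, which had 0 in each flox library. Ctrb1, which encodes chymotrypsinogen, had 5254 FPKM in HKO 3, 52.3 in HKO 2, 2.44 in HKO 1 and 0 to 0.425 FPKM in flox. All 15 tested members were higher in the libraries labelled HKO as fitted, with a median of 4.54 (limma camera, adjusted p = 0.000128, 6.95e-07 without HKO 3, and adjusted p = 0.695 with an estimated correlation), and 0 passed adjusted over the list alone. Values of the trypsin genes are uncertain, since reads of near-identical copies may be shared.

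**Figure D3:**
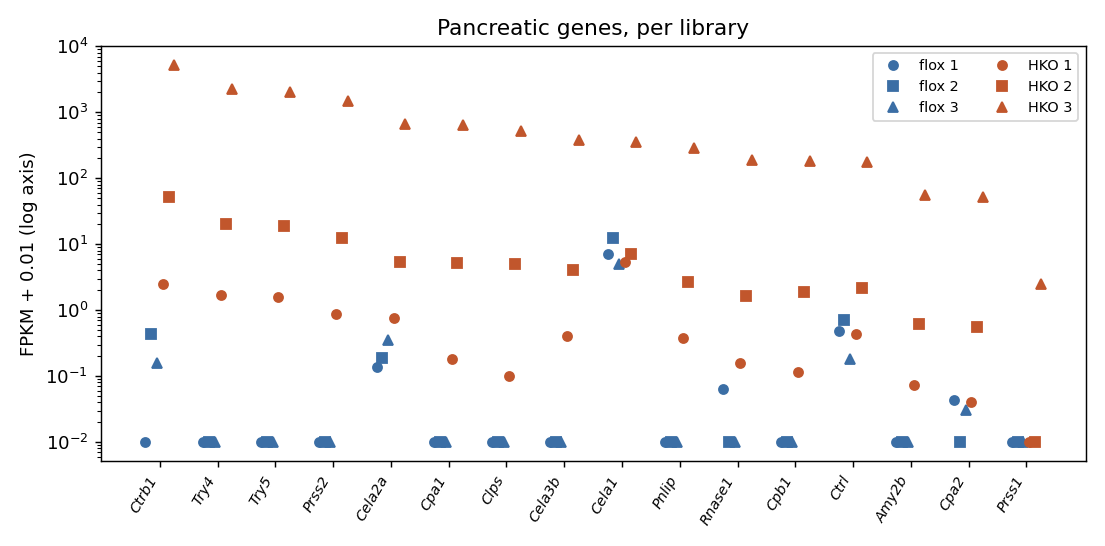
FPKM + 0.01 (vertical axis, logarithmic) of the 16 pancreatic genes (horizontal axis) in each of the 6 libraries; colour gives the label and the symbol the replicate number. HKO 3 lay above the other libraries for each gene, with Ctrb1 at 5254 FPKM against 52.3 in HKO 2.

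Fold changes also followed gene length. From the shortest to the longest decile of the tested genes, the median log2 fold change of HKO against flox went from -0.24 to 0.38, with its lowest value, -0.33, in decile 2. The slope of each library's deviation on log2 length was -0.040 and -0.142 per doubling in flox 1 and 2, 0.047 in flox 3, and 0.038, 0.049 and 0.049 in HKO 1, 2 and 3. After this trend was removed from each library, a correction chosen after seeing the data, limma again called 2 genes, the same as before, and camera called 18 lists, of which 0 passed with an estimated correlation. Of these, 17 were among the 19 and had the same direction. Hepatocyte identity and the interferon response were lost, and fibrosis was gained (adjusted p = 0.0324, and adjusted p = 0.774 with an estimated correlation).

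**Figure D4:**
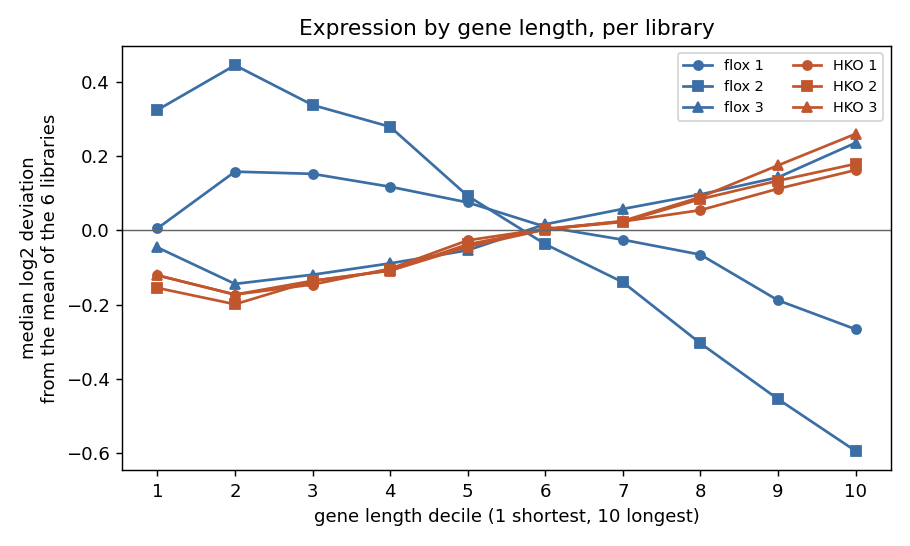
Median over genes of log2(FPKM + 0.5) minus the mean of the 6 libraries (vertical axis) for each decile of the tested genes by length (horizontal axis, 1 shortest, 10 longest), one line per library; colour gives the label and the symbol the replicate number. Flox 1 and flox 2 fell below the other libraries in the longest decile, and flox 3 ran with the libraries labelled HKO.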

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

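Settings that involve the length correction, the joint omission of flox 2 and HKO 3, and the library weights were chosen after seeing the data. Elavl1 stayed higher in the libraries labelled HKO and short of the threshold in all 22 alternatives run for it (log2 fold change 0.32 to 1.04, limma adjusted p 0.0516 to 0.640). The 2 called genes were shared by all fits on 6 libraries, except that the replicate block lost Saa3 (adjusted p = 0.144) and left 0 genes lower and Cyp2b13 alone higher; with the length correction added, 0 were lower too. Equal replicate numbers did not pair the samples: the correlations of their deviations were -0.042, -0.090 and 0.070, and not every sample correlated best with its own number. Genes higher numbered 4 with equalized FPKM sums, 4 with totals without the 50 most abundant genes, and 2 without the variance trend. These 2 scalings moved the median log2 fold change of all genes to 0.34 and 0.33. A threshold of 0.1 gave 8 higher and 8 lower. Leaving out 1 library gave 0 to 2897 genes higher and 0 to 2678 lower, the high ends without flox 3, where 125 of 133 named genes passed that had not; leaving out flox 2 and HKO 3 gave 0 and 0. Array weights gave 5060 and 4993, but put a weight of 1231 on flox 1 and 0.036 to 0.91 on the others, and voom with quality weights gave 3967 and 3828. Lists higher and lower were 0 and 0 with an estimated correlation, and quantile normalization left 7 lower. Apart from hepatocyte identity, lists that changed direction had not passed; their adjusted p, by camera, follow. No filter: bile acid 0.779, methionine 0.979, unfolded protein response 0.617. Filter at 2 FPKM: stellate 0.915, endothelium 0.887, male-biased 0.862. Endothelium also turned with equalized sums (0.868) and without the 50 genes (0.862). Quantile normalization: mitochondrial genome 0.153, gluconeogenesis 0.254, stellate 0.989, endothelium 0.720, hepatocyte identity 0.167. Length correction, then with the block: mitochondrial genome 0.815 and 0.753, B cells 0.815 and 0.911. Without flox 2 and HKO 3: bile acid 0.525, fibrosis 0.892, B cells 0.317. Leaving out 1 library gave ranges of 0.000125 to 0.696 for cell cycle, 0.268 to 0.964 for bile acid, 0.438 to 0.944 for B cells, 0.123 to 0.978 for blood, 0.677 to 0.970 for stellate, 0.50 to 0.970 for endothelium and 0.433 to 0.811 for the unfolded protein response. Of named genes, which had not passed, mt-Nd4 turned to a log2 fold change of 0.0297 with equalized sums, 0.0132 without the 50 genes and 0.359 after quantile normalization, and Bpgm to 0.0911 and 0.0755 with the first 2. Beyond the settings' construction the cause was not tested. Robust moderation was not run for the lists. What depth limits was not tested.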

Other observations

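Tests chosen only after the result was seen were those of the 2 called genes over other splits, the 3 tests on Elavl1, those of genotype, fragmentation and single libraries for the length trend, and the 3 tests on pancreatic transcripts; how to read the last of these was settled after its p was seen. Some acute-phase genes stood apart in flox 3. Saa2, a serum amyloid A gene, was at 561 FPKM there, against 20.5 and 20.9 in flox 1 and 2 and 0.964 to 1.98 in the libraries labelled HKO. Fgb, a fibrinogen chain, had 3684 FPKM in flox 3 and 615 to 938 FPKM in the other libraries, and Crp (C-reactive protein) 126 and 14.9 to 38.1. Others were lowest of the flox libraries there: Hamp, which encodes hepcidin, had 679 FPKM against 3535 and 5508, Hpx 6867 against 10251 and 12139, and Saa4 34.0 against 79.0 and 44.3. Mt1, a metallothionein, and Pnpla2, the main triglyceride lipase, were also highest there, at 1885 FPKM against 408 and 497 in flox 1 and 2, and at 276 FPKM against 56.1 and 83.6.

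Other groupings of the libraries bear on the counts. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many as 2 genes, the real one, and the highest other gave 1. For gene lists, 1 of the 10 splits gave as many as 19, again the real one, but the highest other gave 16 and the lowest 10. Of the 10 splits of the 5 libraries without flox 3, 1 gave as many as 5575 genes, the real one, and the highest other gave 1. That real split also separates the negative length slopes of flox 1 and flox 2 from the positive ones of the HKO libraries. With 10 splits no share under 0.05 can be reached. The simulations called 0.200 lists on average, but they drew genes independently and so cannot show which correlation these libraries have. The other splits cannot either, since each keeps part of any difference between the groups. Correlations estimated from the data ran from -0.177 (adipose tissue) to 0.988 (pancreas), so the preset 0.01 may be too low for some lists. With the estimated correlation 0 lists were higher and 0 lower.

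Elavl1, at 0.67 above flox on the log2 scale in the libraries labelled HKO, did not show the loss that the labels name. A larger share of all non-hepatocyte cell types together in those libraries is argued against by their markers, which moved apart: the upper quartile of the macrophage list was -0.28, while the median of the cholangiocyte list was 0.25. A larger share of a single cell type, such as cholangiocytes, stays open. The macrophage marker Adgre1, given above, hardly differed between the groups. A length-linked difference in coverage remains open: of the 500 tested genes nearest in length, 25.4% had a log2 fold change at least as high, and their median was 0.31. An exchange of the labels of the 2 groups cannot be told apart from it. Elavl1 was lower in all 3 libraries labelled flox (a fitted ratio of 0.627). No other value was taken as a mark of the genotype. Transcription of the recombined allele was not tested, because the values carry no exon.

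The trend with gene length may be technical. A few abundant short genes as the cause are argued against for flox 2, whose slope among the 9999 genes with a mean under 10 FPKM was still -0.110 per doubling. For flox 1 this cannot be told apart, as its slope was -0.028 there and only -0.040 over all genes; the average of both was -0.0692. Genotype and length cannot be told apart with 3 libraries each: the slopes differed by 0.091 between groups, with an exact two-sided permutation p of 0.2 over the 20 assignments, and flox 3 had the slope of the libraries labelled HKO. Fragmentation of the RNA in flox 1 and flox 2 stays open as well, as gene sums hold no position along transcripts; flox 2 had reads in 16608 genes, the fewest.

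The pancreatic transcripts of HKO 3 also appeared in HKO 2. Over the 14 genes with under 1 FPKM on average in flox, the log2 ratio of HKO 3 to HKO 2 averaged 6.71 with an SD of 0.180; with Cela1, which flox libraries also held and whose ratio was 50.3, the SD was 0.324. An effect of genotype of one size in the 3 libraries labelled HKO is argued against by the ratio itself, a median of 108 over the 14 genes. Reads of HKO 3 assigned to HKO 2 would give 1 fraction for every gene; over 11 genes with at most 3 reads in flox it was 0.858%, with a p of 0.285 for differences between genes over 100000 resamples, which cover counting error alone and treat reads as independent. A single source of the RNA cannot be told apart from such assignment, which makes the ratio constant whatever the source. Whether pancreatic tissue or liver cells made the transcripts in HKO 3 was not tested, as no gene outside the pancreas list was examined for it.

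A hypothesis set beforehand was that loss of HuR, which binds AU-rich RNA, lowers transcripts with AU-rich 3' UTRs. Among 11443 tested genes with an annotated 3' UTR of at least 50 bases, 3297 held the heptamer TATTTAT. Length-corrected fold changes were used, a correction chosen after seeing the data, and the difference without it was not computed. Within 20 bins of 3' UTR length, their length-corrected log2 fold change in the libraries labelled HKO lay 0.17 above that of genes without it (SE over bins 0.013), the opposite direction. The highest other of the 10 splits gave 0.16, with flox 1 and 2 on one side, so the difference may belong to those 2 libraries and not to the genotype, and the labels themselves are in question through Elavl1.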
